A study of Homo sapiens with 4 samples.

How the data were processed

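Total RNA of 4 cell cultures was hybridised to 1 array each, and per the file headers all 4 arrays were on 1 slide and read in 1 scan. The authors deposited scanner output made with Agilent Feature Extraction 11.0.1.1, per the file headers, under a 1-colour gene expression protocol. Its spot values are intensity on a linear scale, and per the file headers the processed signal is background-subtracted, with a small positive value in place of signals at or below background. The authors also deposited a table of log2 values for 28825 probes. Its columns correlated above 0.999 with log2 of the same arrays' processed signals. Their quartiles were nearly equal, with medians of 8.24 for each array, so the values are quantile normalized and not centred per gene. The software, any offset and the filter behind that table were not given in the sources used here. Aligners and read depth do not apply to arrays. The files name the assembly hg19, while the reference table of gene names was of GRCh38.p14, so names only were taken from it and no coordinates are given.

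Each array held 44495 spots, of which 1377 were controls and left out. Spots with an outlier or manual flag (444, 372, 380 and 449 on the HepG2 control, HepG2 FXR, SK-Hep-1 control and SK-Hep-1 FXR arrays) were left out as well. Processed signals were set to log2 minus the array's 75th percentile, and spots of a probe were averaged. Of 34127 probes 34114 had a value on all arrays. Accessions or symbols named 25761 of them, and 8353 stayed unnamed. Among 24455 probes designed on curated mRNA accessions 23853 were named. The probe with the highest mean over the 4 arrays stood for its gene, giving 19737 genes, of which 4988 had at least 2 probes. Probes of a gene disagreed with a robust SD of 0.34 log2 in both lines. Of 999 probes printed 10 times, from 831 to 884 per array entered the spot SD. Their median SD was 0.0664, 0.0587, 0.0727 and 0.0778 log2 on the 4 arrays. These SDs measure spots on an array, not cultures.

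The position of disagreeing repeated spots was examined after the data were seen. Counted from the first row, blocks of 10 rows were taken until a block had under 2% of repeated spots over 0.5 log2 from their probe's median. These rows, and columns in which at least 8% of repeated spots did so, were joined into 1 area. Later blocks from rows 391, 431 and 461 had 2.99%, 2.26% and 2.42% and were not included. It held 12727 spots (29.5%). Results were recomputed from the spots outside it where probes remained there. Lists with fewer than 5 measured members outside it were not ranked: gluconeogenesis in both lines and repressed FXR targets in HepG2.

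Within a line, a gene was counted where its probe was well above background on at least 1 of the 2 arrays and the log2 difference was at least 1 or at most -1, with no test since each group had 1 array. Where 1 array was not well above background, the fold is a bound. It sets the bright array's value against the higher of the dim probe's value and the lowest signal among probes well above background on the dim array. The common effect and the cell line effect were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p at 0.05) on all 4 arrays, with cell line and vector as terms. Genes tested were well above background on at least 2 arrays. No p-value can include the spread between cultures of 1 group. Cultures, slide and scan gave no batch to use as a block, since all arrays shared 1 slide and 1 scan.

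A set of 32 gene lists was ranked within each line by the percentile of the median among 10000 random lists of the same size, matched in 20 bins of mean expression. The lists cover FXR targets and bile acids, lipid and sugar metabolism, clotting, hepatocyte, endothelial, mesenchymal, epithelial and haematopoietic markers, cell cycle, stress, interferon, inflammation, JAK-STAT, Wnt, TGF-beta, invasion, hypoxia, NRF2, cytochrome P450, nuclear receptors, autophagy, ribosomal proteins and housekeeping genes. A list was taken to stand apart below percentile 2.5 or above 97.5. By chance 1.6 of 32 would be so placed in each line if members varied independently, as in the random lists. Members of a list can vary together, so chance may place more. The common effect on lists was tested with camera (limma) at a preset correlation of 0.01 and with an estimated correlation. Groups, tests, lists and the rule for named genes were set before the data were examined. The rule took NR1H4 and 7 known FXR targets. Within each line it took the 8 largest rises and falls and the 4 largest bounds each way. It also took the 10 genes each way common to both lines, the 10 each way between lines, the 5 each way that moved oppositely, and up to 4 members of every list in each comparison. SLC7A2, TCIM and CR2 were named after their values were seen.

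On simulated data for the common effect with 17641 genes, limma recovered 15 of 50 genes changed by 1 log2 (30%). It recovered 50 of 50 (100%) at each of 2, 3 and 5 log2, with 21 false calls among the others. The simulated spread was drawn from the prior that limma had fitted to these arrays, so the assumptions of the test held by construction. How the test behaves where that prior is wrong was not simulated. In a simulated list of 40 members in HepG2 (17200 genes), no shift gave percentile 89.16, a shift of 0.1 percentile 47.1 and a shift of 0.2 percentile 98.87, while a shift of 0.5 lay above every random list.

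Alternatives were quantile normalization, the authors' table, a percentile over probes detected on all arrays, other detection filters, a floor, the mean of a gene's probes, eBayes with a trend and a fit without the pairing term. The planned normexp correction on mean signals was run on median signals with an offset of 50, since the files hold no mean signals. That change, a median centring and the fit outside the uneven area were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.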

Results

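Gene expression was measured on 4 one-colour Agilent whole-genome arrays of human liver-derived cell lines. HepG2 is a line from a hepatoblastoma, and SK-Hep-1 is a line from a liver adenocarcinoma. Each line had been transduced with a lentivirus that overexpresses FXR (gene NR1H4), the nuclear receptor for bile acids, or with a negative control virus. All 4 cultures received 2 uM GW4064, a synthetic FXR agonist, for 24 h. The 4 groups were HepG2 control, HepG2 FXR, SK-Hep-1 control and SK-Hep-1 FXR, with 1 array per group and so no replicates. Differences between the arrays of 1 line are therefore given as values without a test, as log2 of FXR over control, and the number of arrays limits their precision. Of 34114 probes, 75.85%, 81.59%, 82.96% and 85.36% were well above background on the 4 arrays in that order, and no spot was saturated. The array covered 19737 named genes.

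Part of the array surface was uneven. Repeated spots of 1 probe differed by over 0.5 log2 from that probe's median on at least 1 array in 107 of 1906 cases (5.61%) in the upper 150 of the 532 rows and in columns 77 and 85. Elsewhere 13 of 4498 (0.29%) did so. The probes of 5406 of the 16915 genes measured in both lines (32.0%) lay there. This region is called the uneven area below, and each gene named from it is marked as such. The FXR targets FABP6, SLC51A, SLC51B, KNG1 and NR0B2 and NR1H4 itself lay outside it.

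**Figure D1:**
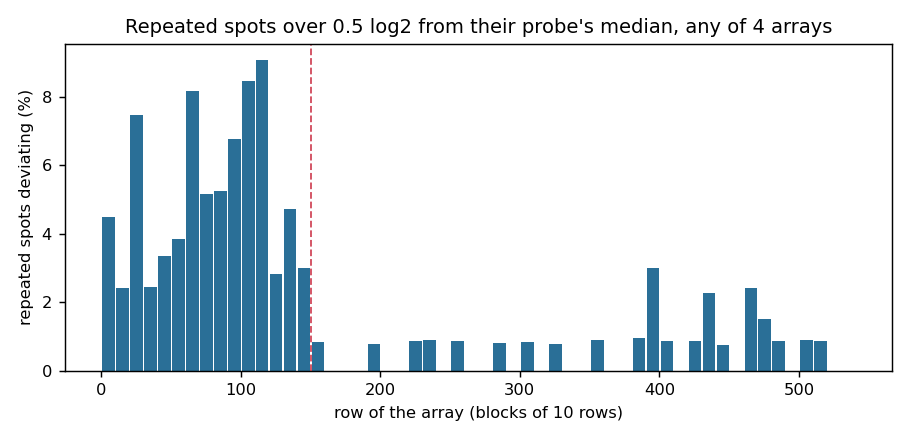
Percent of repeated spots (vertical axis) that lay over 0.5 log2 from the median of their probe on at least 1 of the 4 arrays, by blocks of 10 array rows (horizontal axis). The dashed line marks row 150, and each block before it exceeds 2%, as do the later blocks from rows 391, 431 and 461, which were not counted as uneven.

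The first question was whether the arrays show the transferred gene. NR1H4 was higher with the FXR vector by 2.40 in HepG2 and by 2.66 in SK-Hep-1. Its log2 level, relative to the 75th percentile of each array, was -4.23 and -1.83 on the HepG2 control and FXR arrays. In SK-Hep-1 it was -4.10 and -1.44. The probe was well above background on all 4 arrays. A single probe represents NR1H4, and whether it lies in the transferred coding sequence was not given in the sources used here.

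The HepG2 comparison asks what FXR overexpression adds to agonist treatment in that line. Several known FXR targets of bile acid handling were much higher with the FXR vector. FABP6, the ileal bile acid-binding protein, was higher by 8.52. SLC51A and SLC51B encode the subunits of the basolateral organic solute and bile acid transporter. SLC51A was at least 269-fold higher, with its control array not well above background, and SLC51B was higher by 4.52. KNG1, the kininogen precursor of bradykinin, was higher by 4.49, and NR0B2, the corepressor SHP, by 1.82. FGF19, the intestinal hormone that represses bile acid synthesis, differed by 0.86, and the bile salt export pump ABCB11 by 0.05.

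The activated FXR targets as a list had 7 of 31 measured members at least 1 higher, 1 at least 1 lower and 23 in between. Their median of 0.26 stood at percentile 99.99 of 10000 random lists matched on expression. The bile acid and organic anion transporters had 5 of 15 members higher and 0 lower, at percentile 99.69. Besides SLC51A and SLC51B, the transporter SLCO2B1 was at least 2.73-fold higher, ABCC3 was higher by 1.19, and ABCB1, in the uneven area, by 1.21. Among bile acid synthesis genes 12 of 13 were within 1 of no difference. CYP7A1, the rate-limiting enzyme of that pathway, was lower by -1.20, with its spot in the uneven area.

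Other large differences in HepG2 were of varied function. CRYBG2 was higher by 5.76, although its other probes ranged from -0.05 to 3.17. MFSD2A, a lysophosphatidylcholine transporter, was higher by 4.89 and TRANK1 by 4.43. SAA1, an acute-phase apolipoprotein, was at least 17.8-fold higher, SVOPL at least 28.0-fold and MT4, a metallothionein, at least 8.93-fold. MYBPHL and SAA2, both in the uneven area, were higher by 5.36 and 4.19, and a second SAA2 probe was not well above background on either HepG2 array. The potassium channel KCNK7 differed by -2.58, the zinc finger gene ZKSCAN1 by -2.29, the adhesion receptor ADGRG6 by -2.13 and the gastric proton pump subunit ATP4A by -2.08. CSMD1 differed by -2.04 and DLGAP1 by -1.94. Among uneven-area genes were PLCB4 at -2.07 and KIAA1549L at -1.99, whose other probe read 0.12. SDR42E1 was at least 19.5-fold lower, OR10X1 and FGL2 at least 10.1-fold, and DSPP, in the uneven area, at least 8.68-fold.

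Several other HepG2 lists stood apart. The p53 targets and cell cycle inhibitors had 3 of 27 members higher and 1 lower, at percentile 99.88. GADD45A, a growth arrest gene, was higher by 1.26, CDKN1C by 1.23 and, in the uneven area, BTG2 by 1.06. Coagulation and complement genes had 7 of 25 members higher and 0 lower, with C1R higher by 2.13, the factor B gene CFB by 1.28 and C3 by 1.07. Their percentile was 97.59, against 93.02 under quantile normalization and 65.87 from spots outside the uneven area. Hepatocyte markers had 4 of 20 members higher and 2 lower. Among them TM4SF4 was higher by 3.50, the retinol carrier RBP4 by 2.71 and ITIH3 by 1.86, while albumin (ALB) was at least 4.17-fold lower and the list stood at percentile 60.06. Interferon response genes had 2 of 27 members higher, with OASL at 1.66 and, in the uneven area, IRF7 at 1.31, at percentile 99.35. Fatty acid synthesis genes had 1 of 19 members higher, the uneven-area gene ACSL1. Their percentile of 98.57 became 89.49 outside that area. Gluconeogenesis genes had 1 of 8 higher, the uneven-area gene PCK1 at 1.23, at percentile 98.59. Too few members lay outside that area to rank this list there. At the other end, 31 of 33 ribosomal protein genes were below 0, at a median of -0.10 and percentile 0.00. Under quantile normalization their median was -0.03 and their percentile 3.69. Glycolysis genes had 12 of 18 members below 0, at percentile 0.34, although the aldolase ALDOC was higher by 1.51.

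In all, 530 genes were at least 1 higher and 299 at least 1 lower in HepG2, of 17200 measured. Of these, 221 and 143 had probes in the uneven area. Where a gene at least 1 higher or lower had a second detected probe, 67 of 94 second probes (71.3%) had the same sign, and 42 (44.7%) also differed by at least 0.5 log2.

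The same question was asked in SK-Hep-1. SLC51A was higher by 4.83 and FABP6 by 3.51, SLC51B was at least 2.08-fold higher, and NR0B2 and KNG1 differed by 0.41 and 0.21. FGF19 differed by 0.81, ABCB11 by 0.40, CYP7A1 (uneven area) by 0.74 and the cytokine signalling suppressor SOCS3 (uneven area) by -0.31. SOCS3 differed by 0.26 in HepG2. The activated FXR targets had 6 of 32 members at least 1 higher and 1 lower, and 25 in between, at percentile 80.24. Bile acid and organic anion transporters had 2 of 15 members higher, at percentile 40.94. The activated FXR target that was at least 1 lower was C3, the central complement protein, at -3.47 with its second probe at -2.32.

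Inflammatory transcripts were lower on the SK-Hep-1 FXR array. Of 27 measured genes of the NF-kB and acute phase list, 14 were at least 1 lower and 1 at least 1 higher. Their median of -1.16 stood at percentile 0.00. The serum amyloid gene SAA1 differed by -3.84. In the uneven area were the neutrophil chemokines CXCL6 at -4.72 and CXCL8 at -4.61, the cytokine IL1B at -4.05, and SAA2 at -4.33. Outside that area 11 of 21 members were at least 1 lower, with a median of -1.18 and percentile 0.00. Beyond the list, the myeloid growth factor genes CSF3 and CSF2 differed by -5.85 and -4.55. A second CSF3 probe read -4.93 in SK-Hep-1 and -4.03 in HepG2. It was well above background on both control arrays and on neither FXR array, so these are not measured sizes. Haematopoietic markers had 0 of 19 members lower or higher by 1, at a median of 0.20.

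Proliferation genes were lower too. Of 38 cell cycle genes 36 were below 0 and 4 at least 1 lower, with a median of -0.64 and percentile 0.00. The checkpoint kinase BUB1B differed by -1.22, the ribonucleotide reductase subunit RRM2 by -1.11 and, in the uneven area, the mitotic kinase CDK1 by -1.08. MKI67 differed by -1.02, but its other probes read 0.14 and 0.18. The list of TGF-beta and YAP targets had 2 of 22 members lower, the uneven-area genes THBS1 at -1.27 (other probe 0.12) and PMEPA1 at -1.06, and its percentile of 0.02 became 7.66 outside that area.

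The ER stress and amino acid response stood highest in SK-Hep-1, at a median of 0.57, above every random list. It had 6 of 27 members higher and 1 lower. The stress transcription factor DDIT3 was higher by 2.47, the glutathione-degrading enzyme CHAC1 by 1.42 and, in the uneven area, ATF3 by 1.46, although its other probes ranged from -0.08 to 1.88. The serine synthesis gene PSAT1, in the uneven area, differed by -2.18. Bile acid synthesis genes stood at percentile 99.96, with 2 of 14 higher and 0 lower. They were CH25H at 1.32 and, in the uneven area, AKR1C4 at 1.16. Hepatocyte markers had 7 of 28 members higher and 2 lower, at percentile 98.43. APOH was at least 7.46-fold and the fibrinogen chain FGG at least 4.01-fold higher, while the uneven-area gene GC was at least 2.58-fold lower. Interferon response genes had 3 of 27 higher and 2 lower, with IRF9 at 1.32, and their percentile of 98.91 became 83.32 outside the uneven area. Autophagy and lysosome genes had 0 of 26 beyond 1, and their percentile of 98.44 became 96.43 outside the uneven area. All 33 ribosomal protein genes were above 0, at a median of 0.26. Under quantile normalization 17 were above and 16 below 0.

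The largest single difference in SK-Hep-1 was that of CEMIP, a hyaluronan-binding protein gene, at 13.21, from a level of -4.87 to 8.34. In HepG2 it was at least 7.35-fold higher. A second CEMIP probe was not well above background on any array. KPRP was higher by 4.22, the lysosomal glycoprotein GPNMB by 3.91, TMT1A by 3.62 and, in the uneven area, the ubiquitin ligase TRIM63 by 4.19. DAZAP1 was higher by 4.94 by 1 probe and by 0.46 by its other. The endothelin receptor EDNRB was at least 11.7-fold and APOF at least 8.63-fold higher. SELENBP1, in the uneven area, was at least 9.02-fold and ZMYM5, also there, at least 13.1-fold higher, and the other ZMYM5 probe was not well above background on either SK-Hep-1 array. DCLK1 differed by -3.69 while its other probes read 0.24 and 0.43. MROH2B was at least 18.8-fold and GDPD2 at least 6.87-fold lower. In the uneven area MAP3K8 was at least 7.65-fold and MUC5B at least 6.87-fold lower.

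Mesenchymal, epithelial and invasion lists held single genes with large differences. The neural cadherin CDH2 differed by -1.84, with its other probe at -2.30, and the epithelial factor ELF3 by -2.89. The urokinase gene PLAU, in the uneven area, differed by -1.83 with its other probe at -1.65, while the integrin ITGB3 was higher by 2.18 and the keratin KRT19 by 1.40. Mesenchymal markers stood at percentile 12.90, epithelial markers at 87.51, and metalloproteases and invasion genes at 26.38.

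In SK-Hep-1, 795 genes were at least 1 higher and 471 at least 1 lower of 17873 measured, and 421 and 280 of them lay in the uneven area. The scaling left the median of all genes at 0.11. Of the counted genes 62.8% were higher, against 49.3% (605 higher, 621 lower) under quantile normalization and 54.7% under median centring, and the cause was not tested. Relative to that shift the list medians were -1.27 for NF-kB and acute phase, -0.74 for cell cycle, 0.46 for ER stress, 0.43 for bile acid synthesis and 0.15 for ribosomal proteins.

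**Figure D2:**
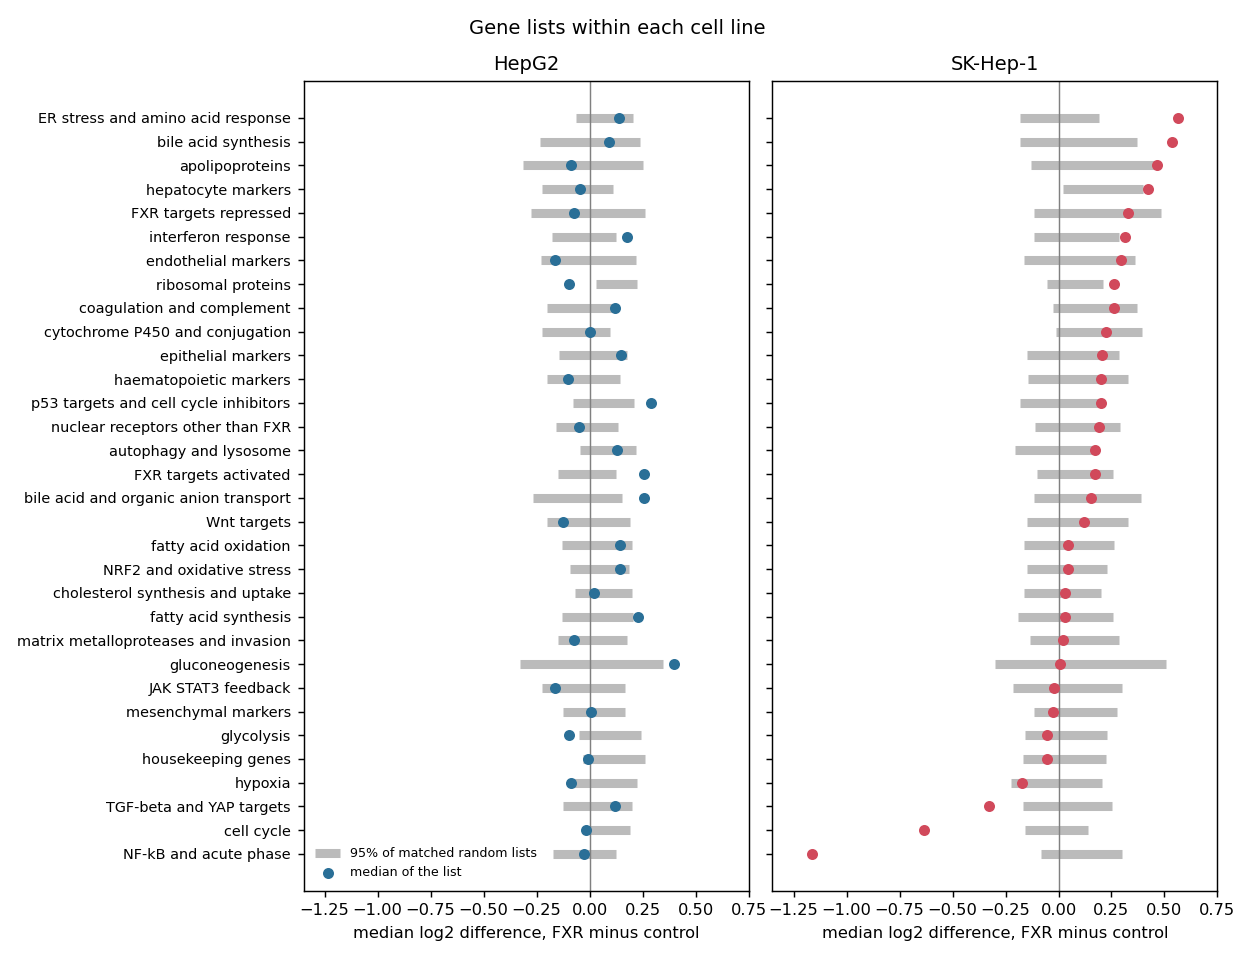
Median log2 difference, FXR minus control vector (horizontal axis), of each gene list (vertical axis) in HepG2 and in SK-Hep-1, with grey bars for the middle 95% of 10000 matched random lists. In SK-Hep-1 the NF-kB and acute phase list lies at -1.16 and ER stress at 0.57; the ribosomal protein median of 0.26 there is 0.01 under quantile normalization.

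The effect common to both lines included FXR targets. In limma with cell line as a block, NR1H4 rose by 2.53 (SE 0.29, adjusted p = 8.05e-08) and FABP6 by 6.01 (SE 0.48, adjusted p = 1.68e-12). SLC51A (adjusted p = 3.08e-16), SLC51B (adjusted p = 6.76e-06) and NR0B2 (adjusted p = 0.0433) rose as well, and so did CEMIP (adjusted p = 2.78e-09), far more in SK-Hep-1. The CEMIP value rests on 1 probe, which was not well above background on the HepG2 control array. The chloride channel gene CLIC3 rose by 2.37, CRYBG2 by 4.40, TMT1A by 2.68, the semaphorin SEMA3B by 1.86, the matrix protein MATN2 by 1.61 and the heparan sulfatase SULF2 by 1.58. In the uneven area TCEA2 rose by 2.99 and TNS2 by 1.92. Each of these had the same sign in both lines.

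A total of 86 genes were at least 1 higher in both lines, against 17.17 if the lines were independent, and 29 of them (33.7%) lay in the uneven area. In contrast, of 31 genes at least 1 lower in both lines, against 5.41 if independent, 27 (87.1%) lay there. Opposite differences exceeded their count as well (57 against 19.27), so an excess over independence does not by itself measure a shared response. With detection on all 4 arrays, 46 genes were at least 1 higher in both lines, against 9.29. Ranked by the smaller of the 2 falls among genes well above background on all 4 arrays, the first 10 genes were in the uneven area. They were SLC14A2, UCHL1, IL33, PPY, OR7G2, BORCS8, PVALB, FBXL14, ACSM2B and OLFML1, with a fitted fall of -1.72 for SLC14A2. The other SLC14A2 probe, outside the area, read -0.24 and 0.24. From spots outside the uneven area, a choice made after the values were seen, 7 genes were at least 1 lower in both lines, against 2.14 if independent. The largest were TCIM (-1.22 in HepG2, -2.46 in SK-Hep-1), the cationic amino acid transporter SLC7A2 (-1.06 and -2.19) and the complement receptor CR2 (-1.05 and -2.17).

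In the gene list test camera with its preset correlation, activated FXR targets rose (adjusted p = 5.75e-06) and so did bile acid and organic anion transport (adjusted p = 0.00799). These 2 lists stood apart in HepG2 only, at percentiles 99.99 and 99.69, against 80.24 and 40.94 in SK-Hep-1. Of the FXR targets 6 of 31 passed over all genes and 9 adjusted over the list alone. The p53 targets and cell cycle inhibitors (adjusted p = 0.00837) and coagulation and complement (adjusted p = 0.0215) rose, with 2 members each past the threshold over all genes and 2 adjusted over the list alone. In HepG2 they stood at percentiles 99.88 and 97.59, against 97.25 and 75.76 in SK-Hep-1. KNG1 and C3 were members of both the FXR target and the coagulation lists. GADD45A rose by 1.18 (adjusted p = 0.0155). The NF-kB and acute phase list fell (adjusted p = 6.1e-09), with 9 of 27 members past the threshold in either direction and 12 adjusted over the list alone. Among the 9, the uneven-area gene ICAM1 rose by 1.31 (adjusted p = 0.00613 in limma). Cell cycle genes fell (adjusted p = 2e-06) with 0 of 38 past the threshold in limma. The falls of both lists came mostly from SK-Hep-1. In HepG2 6 of 25 NF-kB and acute phase members were at least 1 higher and 1 lower, while cell cycle genes had 21 of 38 members below 0, at percentile 3.33 and at 1.74 under quantile normalization. Among the NF-kB members, both in the uneven area, CXCL8 fell (adjusted p = 0.000266) and IL1B fell by 2.07, though in HepG2 they differed by -0.38 and -0.09. With an estimated correlation each of the 6 lists had an adjusted p = 0.866 in camera, and no list passed. That setting uses the 1 residual degree of freedom, so a list could hardly pass. For transport the estimated correlation of -0.0667 was below the preset, yet the unadjusted camera p went from 0.000999 to 0.1765. This setting therefore says little about correlation within lists.

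By limma 251 genes rose and 116 fell of 17641 tested, with 1 residual degree of freedom per gene, so p-values cover these 2 lines only. The fitted prior had 43.3 degrees of freedom, so each p-value rests mostly on a spread pooled over all genes. A gene with unlike responses in the 2 lines could still pass, as CEMIP and the uneven-area gene CXCL8 did. Under quantile normalization 0 genes passed, with 1339 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0976.

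**Figure D3:**
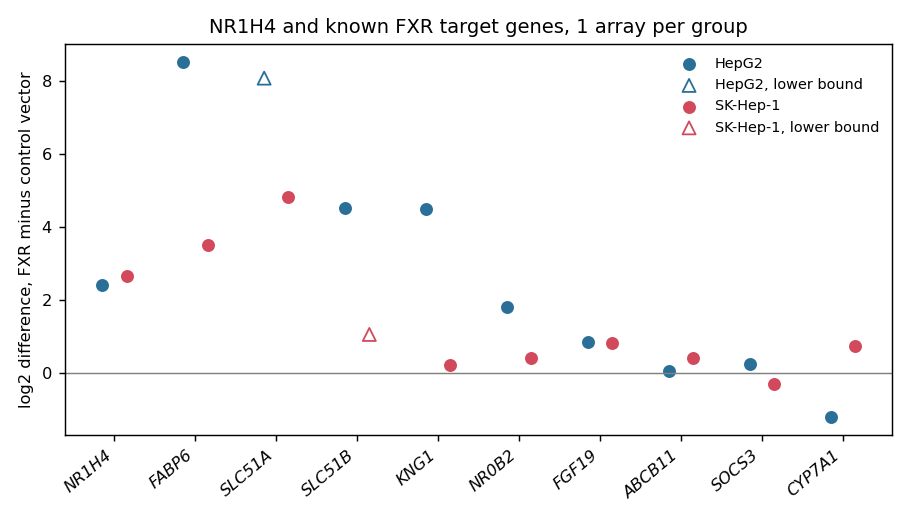
Log2 difference, FXR minus control vector (vertical axis), for NR1H4 and known FXR targets (horizontal axis) in HepG2 and SK-Hep-1, 1 array per group; triangles are lower bounds where 1 array was not well above background. FABP6 lies at 8.52 in HepG2 and 3.51 in SK-Hep-1, and ABCB11 at 0.05 and 0.40.

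The lines were also set against each other. SAA1 was at least 17.8-fold higher with FXR in HepG2 and differed by -3.84 in SK-Hep-1. CDH2 differed by 1.52 in HepG2 and -1.84 in SK-Hep-1, C3 by 1.07 and -3.47, and ELF3 by 0.75 and -2.89. The splicing factor TRA2A was at least 5.22-fold lower in HepG2 and higher by 2.65 in SK-Hep-1, and ZKSCAN1 differed by -2.29 and 1.65. NF-kB and acute phase genes stood at percentile 51.25 in HepG2 and 0.00 in SK-Hep-1, and ER stress genes at 83.31 and above every random list. Several NF-kB list members, among them CXCL8 and IL1B in the uneven area, read near background on the HepG2 control array. For these HepG2 left little room for a fall.

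Differences in opposite directions of at least 1 were seen in 57 genes, against 19.27 if independent, and 39 of the 57 (68.4%) lay in the uneven area. Across the 16915 genes the differences correlated with Pearson r = 0.13 and Spearman rho = 0.10, described without a p since genes are not independent replicates. The difference between lines has no residual and was not tested.

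**Figure D4:**
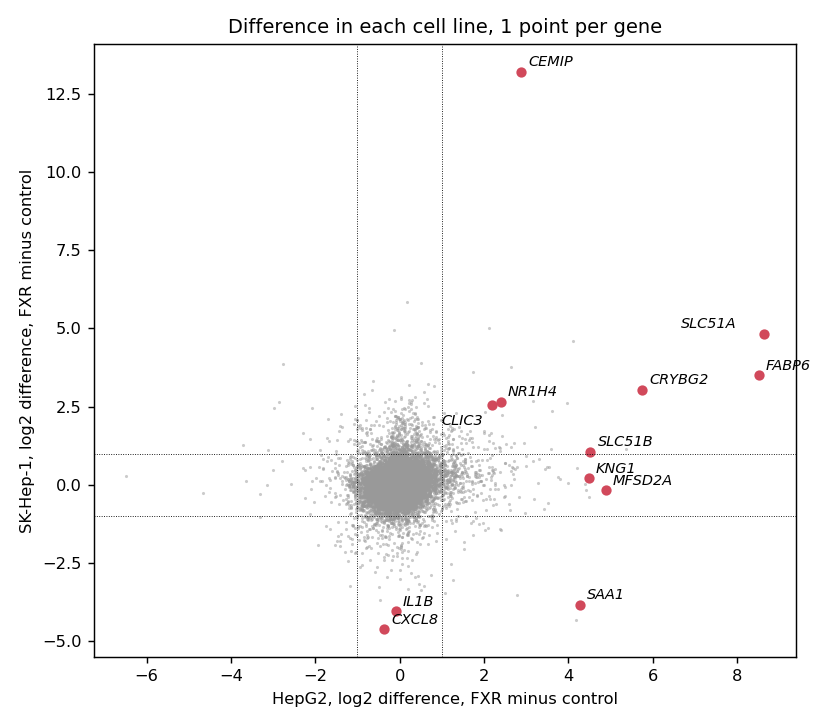
Log2 difference, FXR minus control vector, in HepG2 (horizontal axis) and SK-Hep-1 (vertical axis) for 16915 genes, values below background plotted as measured; dotted lines mark a difference of 1. FABP6 lies at 8.52 and 3.51, CXCL8 at -0.38 and -4.61.

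The last comparison was between the cell lines, with vector as a block. Protease inhibitor SPINK6 was higher in HepG2 by 11.12 (SE 0.30, adjusted p = 9.65e-32), the neuronal pentraxin NPTX1 by 9.69 and TRIM29 by 9.73. The chemokine receptor ACKR3 was at least 498-fold higher with the control vector and at least 1540-fold with FXR. SK-Hep-1 was higher for G0S2, an inhibitor of lipolysis, by at least 5320-fold with the control vector and 7800-fold with FXR. The proteoglycan SRGN was higher there by at least 3390-fold and 4780-fold. The surface marker THY1 was at least 1620-fold higher with the control vector.

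Mesenchymal markers were lower in HepG2 by camera (adjusted p = 0.0200). With an estimated correlation, and so 1 residual degree of freedom, the camera adjusted p was 0.842. Of the 26 markers, 23 passed in limma over all genes and 24 adjusted over the list alone. SPARC differed by -5.47 (adjusted p = 1.24e-20) and, in the uneven area, LOX by -5.13, while S100A4 went the other way at 7.31. Of 20 epithelial markers 17 passed (camera adjusted p = 0.155), with MAL2 higher in HepG2 by 6.22 and KRT19 lower by -8.63. Endothelial markers passed in 9 of 16 with no direction as a list (camera adjusted p = 0.983). The uneven-area gene ROBO4 was at least 29.7-fold higher in SK-Hep-1 with the control vector, and ESAM was higher in HepG2 by 3.19. NRF2 targets passed in 13 of 26 with a median of -0.18 and no call by camera (adjusted p = 0.153), although AKR1C3 and NQO1 were higher in HepG2 by 7.24 and 5.54. The shares of endothelial and NRF2 genes that passed were close to that of all genes tested.

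Hepatocyte markers did not divide the lines as a list (camera adjusted p = 0.770). Of all genes, 82.6% were well above background on the HepG2 control array and 86.9% on the HepG2 FXR array. Of 35 hepatocyte genes on the array, 19 were well above background on both arrays labelled HepG2, and 15 on neither. Those 15 were TTR, TF, APOA2, APOB, APOH, FGA, FGB, FGG, AMBP, AFP, HNF4A, TAT, ITIH2, FABP1 and GC, of which TF, APOB, AMBP, TAT and GC lay in the uneven area. AFP, the fetal liver protein, was at least 6.34-fold higher in SK-Hep-1 with the control vector. Albumin (ALB) was well above background on the HepG2 control and SK-Hep-1 FXR arrays only. RBP4 was higher in HepG2 by 6.86 and the urea cycle gene CPS1, in the uneven area, by 7.85. All 16 housekeeping genes were well above background on all 4 arrays.

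By limma 3562 genes were higher and 4931 lower in HepG2 of 17641 tested, against 3680 and 3651 under quantile normalization. The arrays of a line carried different vectors, so these p-values cover the spread between those arrays only. They too rest mostly on a spread pooled over all genes, with a prior of 43.3 degrees of freedom.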

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

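All tests of explanations in this part were chosen after the results were seen.

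Genes with opposite differences and 1 group of unnamed probes stood out. The FXR effect in HepG2 minus that in SK-Hep-1 (log2) was 8.52 for SAA2, 8.11 for SAA1, 6.31 for FHOD3, 3.34 for PCDH20 and 3.58 for LRRIQ1, which read higher in HepG2 and lower in SK-Hep-1. It was -5.51 for TRA2A, -5.42 for LAMB4, -4.52 for PLCB4 (its other probe in SK-Hep-1 read 0.04), -3.80 for ZSCAN23 and -3.93 for ZKSCAN1, which went the other way. These differences were not tested, since each line has 1 pair of arrays. SAA2, FHOD3, PCDH20, LRRIQ1, PLCB4 and ZSCAN23 lay in the uneven area, and SAA1, TRA2A, LAMB4 and ZKSCAN1 did not. For all but SAA2, PLCB4 and ZKSCAN1 at least 1 array was not well above background, so their values rest on background readings and are not measured sizes. The HepG2 direction of LRRIQ1 turned under other settings (-0.006 with normexp), so no rise is claimed for it. Among probes without a gene name, which no comparison uses, 17 of 5900 were at least 1 higher in both lines, against 7.29 if the lines were independent.

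The genes lower in both lines sat close together on the arrays. Of those at least 1 lower in both, 87.1% had their probe in the area where repeated spots disagree, against 32.0% of genes measured in both lines, so uneven hybridisation over part of the arrays is a candidate explanation for most of them. Among those named above, ACSM2B, IL33, FBXL14 and BORCS8 had spots within rows 101 to 122 and columns 69 to 83. Only 3 other probes of these genes lay outside the area, and 0 of them were at least 1 lower in both lines. In HepG2 and SK-Hep-1 they read 0.09 and -0.03 (GRM7), 1.21 and 0.39 (PAX2), and -0.24 and 0.24 (SLC14A2). These 3 probes did not repeat the fall. For the other genes a lower transcript level with the FXR vector stays open, because no such probe was there to test it. Recomputed from spots outside the area alone, 7 genes were at least 1 lower in both lines, against 2.14 if independent. They are not a remainder of the first count, and for these 7 no technical explanation was tested.

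As a list, inflammatory transcripts were lower in SK-Hep-1 and not in HepG2. On the HepG2 control array IL1B (-4.67) and CXCL8 (-4.59), both in the uneven area, read near the lowest detected level of -5.91. Their SK-Hep-1 control levels were 3.77 and 0.63. CXCL6 and IL1A, also in that area, and SAA1 were not well above background on the HepG2 control array. For these genes a fall as large as in SK-Hep-1 could not have shown in HepG2. Not every list member read so low there: ICAM1, in the uneven area, read -0.67. Scaling of the arrays is argued against by the median of the list in SK-Hep-1, which stayed at -1.126 under quantile normalization. Uneven hybridisation over part of the arrays is argued against by a median of -1.179 from spots outside the area. Fewer blood cells in the SK-Hep-1 FXR sample is not an explanation the design offers, since both SK-Hep-1 samples were cultures of 1 cell line. Haematopoietic markers (median 0.20) could not test it, as they read about as high on the HepG2 arrays and so would not follow blood cells. Open hypotheses, untested with 1 culture per group, are that FXR lowers these transcripts in SK-Hep-1 cells, or that the 2 cultures differed in an inflammatory state for another reason, which may include the virus.

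Many transcripts typical of hepatocytes were at background on the arrays labelled HepG2. Weak labelling or hybridisation is argued against by 82.6% of genes well above background on the HepG2 control array, and uneven hybridisation by 10 of the 15 genes at background having probes outside the area. Labels of the cell lines exchanged are argued against too, since 0 of the 15 lay above the 75th percentile signal on both SK-Hep-1 arrays. The tables cannot separate other cells than the label says from HepG2 cells that had lost these transcripts, as 19 of 35 hepatocyte genes were well above background on both HepG2 arrays and neither explanation sets that number. No biological explanation was tested, since the design gives no group that bears on it.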

How the results depend on the processing

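Of the results below, normexp on median signals, median centring and the fit outside the uneven area were added after seeing the data. Counts depended on the setting more than directions did. With normexp, HepG2 had 264 genes higher and 116 lower, SK-Hep-1 276 and 179, and both lines shared 30 higher, 12 lower and 10 opposite. With detection on both arrays of a pair HepG2 had 339 higher, and with all 4 arrays detected 46 genes were higher in both lines and 27 opposite. With no detection filter 523 were lower in HepG2, 55 lower in both lines and 116 opposite. The authors' table gave 519 higher in SK-Hep-1. Outside the uneven area HepG2 had 339 higher and 189 lower, SK-Hep-1 406 and 232, with 7 lower in both and 22 opposite. That setting also tests fewer genes (13721 in limma).

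The limma counts for the common effect (251 rose, 116 fell) were 0 and 0 under quantile normalization (1339 at an unadjusted p under 0.05) and in the authors' table (1360). They were 148 and 63 with normexp, 74 and 33 with the percentile over detected probes, 21 and 3 with median centring, and 151 and 50 outside the uneven area. They were 152 and 77 with detection on all 4 arrays and 15 and 7 with no filter. With no replicate block, the pairing term left out, they were 0 and 0, with 62 at an unadjusted p under 0.05 by limma. The fitted prior degrees of freedom ranged from 1.86 with no block to infinity with normexp, and fell to 3.87 under quantile normalization; the cause of the changed counts was not tested. With an estimated correlation 0 gene lists passed in camera, but that setting has 1 residual degree of freedom and a list could hardly pass. Leaving out either line leaves 1 pair with no residual, and so no count.

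HepG2 LRRIQ1 turned to -0.006 with normexp and -0.24 with a floor. Other probes outside the uneven area turned PLCB4 in HepG2 to 0.079, SAA2 in HepG2 to -0.172, and in SK-Hep-1 SLC14A2 to 0.229 and ZMYM5 to -0.107. Of these probes only that of SLC14A2 was well above background in the named line, so the others say nothing of direction. A block for slide or scan was not run, since all arrays shared 1 of each. Signal over background limits genes seen on 1 array of a pair, which have bounds only.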

Other observations

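Cytochrome P450 genes gave mixed values in HepG2. CYP3A7, the fetal form of the drug-metabolising enzyme, was higher with FXR by 1.28 and, in the uneven area, CYP3A5 by 1.47. In that area CYP2E1 was at least 4.69-fold higher and the bile acid sulfotransferase SULT2A1 differed by -1.33. The list stood at percentile 82.60 in HepG2 and 53.28 in SK-Hep-1. Of the nuclear receptors other than FXR, the fat cell regulator PPARG, in the uneven area, was higher in HepG2 by 1.74, with its other probe at 1.53. The clock repressor NR1D2 differed by -0.99 in HepG2 and by 1.12 in SK-Hep-1, with its other probe there at 2.17. That list stood at percentiles 31.21 and 79.31.

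Of NRF2 and oxidative stress genes, the cystine transporter SLC7A11 differed by -1.69 in HepG2 and 0.90 in SK-Hep-1, and the quinone reductase NQO1 by 0.58 and -1.17. The list stood at percentiles 91.94 and 49.63. Cholesterol synthesis stood at 26.54 and 53.37, with 25 of 26 and 26 of 26 members within 1. Fatty acid oxidation stood at 90.33 and 44.43, hypoxia at 3.11 and 6.47, JAK STAT3 feedback at 7.72 and 27.28, Wnt targets at 10.26 (1.93 outside the uneven area) and 49.10, and endothelial markers at 7.72 and 91.40. Repressed FXR targets stood at 32.51 and 78.55 and apolipoproteins at 34.11 and 97.18. Fatty acid synthesis and gluconeogenesis stood at 46.25 and 26.89 in SK-Hep-1, glycolysis at 18.17 and housekeeping genes at 19.66. In HepG2 housekeeping genes stood at 4.62, mesenchymal markers at 46.08 and haematopoietic markers at 18.48. Epithelial markers stood there at 95.16, invasion genes at 14.64, TGF-beta targets at 85.01, cell cycle at 3.33 and autophagy at 71.53. In SK-Hep-1, p53 targets stood at 97.25, transport at 40.94 and coagulation at 75.76.

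The muscle actin gene ACTA2 was higher with FXR by 1.56 in HepG2 and 0.84 in SK-Hep-1. The endothelial adhesion gene ESAM was higher by 1.14 and 1.77, and the liver stress factor CREB3L3 by 2.18 and 0.95. In limma their common rises were 1.20, 1.46 and 1.57 (adjusted p = 0.0155, 0.00192 and 0.00127).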
